A study of Mus musculus with 12 samples.

How the data were processed

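Gene expression was measured by RNA sequencing in 12 libraries of B16 mouse melanoma cells, grown in DMEM with 10% FBS per the labels. They formed 4 groups of 3, control (shRFP) and Sdc1 knockdown (shSdc1) cells, each with and without IFNγ at 10 ng/ml for 24 h. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The number of hairpins and the means of delivery are not given in the sources used here, so effects of a hairpin on other transcripts cannot be separated from those of the knockdown.

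The deposited table holds raw counts per gene, whole numbers, in 56093 entries. The submitters' processing notes name Trimmomatic, HISAT2 2.0.5, HTSeq and the build GRCm39; how each was used, the annotation and the strand setting are not given in the sources used here. Symbols came from a GENCODE M21 (GRCm38) reference and matched 52083 of the entries. A further 3333 Ensembl identifiers had no symbol there, and 677 entries were assembled loci with no Ensembl identifier. Exon length, GC content and transcript sequences were taken from the same reference, and no coordinates are given because its build differs from the one those notes name.

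Counts were scaled by TMM, and genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 14089 genes of the 27472 with a count. A quasi-likelihood model with 1 coefficient per group was fitted over all 12 libraries with edgeR 4.0.16 in R 4.3.3, with 8 residual degrees of freedom and a common biological coefficient of variation of 0.0633. The 5 comparisons were knockdown against control without IFNγ, the same with IFNγ, IFNγ against none in control and in knockdown cells, and the interaction. P-values were adjusted over all genes of a comparison by the Benjamini-Hochberg method at 0.05 with no fold minimum, and two-sided. The SE of a log2 fold change was its size over the square root of F, and levels are TMM-scaled CPM. For large folds from few counts this SE can be smaller than the counting error, so it overstates the precision. Where a group had 0 counts, the fold was computed against 3 counts over the group; with 1 to 3 counts the ratio of counts is given with its 95% exact interval. Such floors and intervals cover counting error only, since PCR copies are not independent molecules. The fitted fold changes used a prior count of 0.125.

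Before the data were examined, 29 gene lists, 18 genes of central interest and the alternatives were fixed. The lists cover interferon and antigen presentation, chemokines, cytokines, checkpoint and lymphocyte ligands, NF-kB targets, pigmentation, syndecans and heparan sulfate enzymes, matrix, integrins, invasive states, cell cycle, p53, stress responses, hypoxia, cholesterol, MAP kinase and Wnt targets, markers of other cell types, mitochondrially encoded genes, histones and ribosomal proteins. A gene of a list is called measured if the filter on low counts kept it. The 25 lists with at least 5 genes measured were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation, and with fry. Their p-values were adjusted over the 25 lists of a comparison. With an estimated correlation 8 lists passed in each comparison between groups and 0 in the interaction, and where a call ended that p is given.

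Named genes followed a fixed rule, and some genes that met it are not reported here. They were the genes of central interest, and the 8 highest and 8 lowest log2 fold changes of each comparison between groups (6 and 6 for the interaction). The latter were taken among genes with an adjusted p under 0.05, a mean of at least 5 CPM in a group, group ranges that did not overlap and an official symbol. Chance separates the ranges of 3 libraries from 3 in 10% of genes. The rule added up to 4 genes per list by size of change among those that passed with a mean of at least 1 CPM; examples were printed for lists that passed the set test and for those on interferon, antigen presentation, checkpoints, chemokines, pigmentation and syndecans.

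The alternatives were DESeq2 size factors and upper-quartile scaling, the DESeq2 1.42.0 Wald test, limma-voom, no filter, a filter of 1 CPM in 3 libraries, a fit of the compared groups alone, the replicate number as a block, a minimum log2 fold change of 1, and leaving out each library in turn. Fits without the assembled loci and ENSMUSG00000119584, and camera without shSdc1 replicate 3, were added after seeing the data. Gene features, random lists and bootstraps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, sequence matches BLAST 2.17.0, and figures matplotlib 3.10.9.

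The steps were tested on simulated data with 50 genes changed at each of 4 sizes. All simulated libraries were drawn from the shRFP means, and genes were changed in 1 group only. In the real comparisons 9.73 to 36.35% of genes passed, far more than were changed in the simulation, so the rates may differ there. The comparisons between groups recovered 44 to 62% of genes changed 1.25-fold, 74 to 80% at 1.5-fold, 88 to 94% at 2-fold and 100% at 4-fold, and 3.12 to 9.09% of their calls were genes not changed. The highest share was that of IFNγ in knockdown cells. The interaction recovered 20, 64, 84 and 100%, with 5.63% of calls not changed. Replicates of a group were compared in pairs; no pair was the same library, with a chi-square per degree of freedom of 2.38 to 8.00, except 63.5 and 62.5 for shSdc1 replicate 3 against replicates 1 and 2.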

Results

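RNA was sequenced from B16 cells, a mouse melanoma line, that carried a short hairpin RNA against Sdc1 or against RFP, the control. Sdc1 encodes syndecan-1, a cell-surface proteoglycan that carries heparan sulfate. The cells were left unstimulated or given IFNγ, the cytokine that induces antigen presentation, at 10 ng/ml for 24 h. The 4 groups held 3 libraries each and are called shRFP, shSdc1, shRFP with IFNγ and shSdc1 with IFNγ. The libraries held 14337771 to 21548940 counts, and 14089 genes were tested. The first principal component, with 75.4% of the variance, separated the libraries with IFNγ from those without, and the second, with 13.9%, separated knockdown from control. Levels are counts-per-million (CPM) values, given as mean ± SD of the 3 libraries of a group, and log2 fold changes are given with their standard error (SE).

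Sdc1 (ENSMUSG00000020592) was lower in every knockdown library than in any control library. It stood at 76.4, 73.9 and 75.9 CPM in shRFP replicates 1 to 3 and at 23.4, 22.1 and 25.7 CPM in shSdc1. With IFNγ it stood at 83.4, 79.6 and 102.7 CPM in shRFP and at 27.0, 25.1 and 25.4 CPM in shSdc1. The log2 fold change was -1.67 ± 0.08 without IFNγ (edgeR adjusted p = 2.5e-11) and -1.77 ± 0.08 with it (edgeR adjusted p = 6.5e-12). The difference between these effects was -0.11 ± 0.12 (edgeR adjusted p = 0.61), so a change of the knockdown by IFNγ was not detectable.

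**Figure D1:**
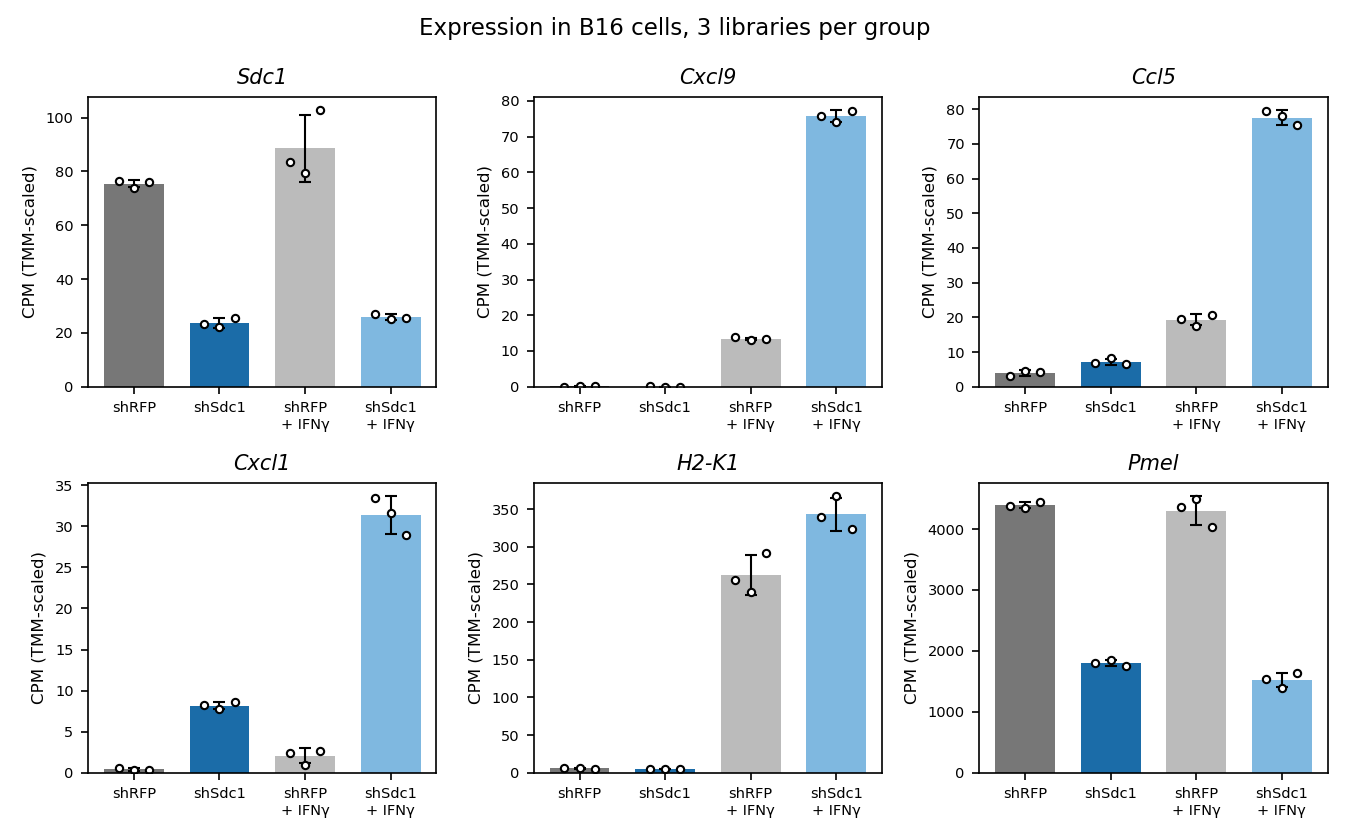
Level of Sdc1, Cxcl9, Ccl5, Cxcl1, H2-K1 and Pmel in CPM, 1 panel per gene and 1 bar per group; bars are means, error bars SD and points the 3 libraries. Sdc1 and Pmel were lower and Cxcl1 and Ccl5 higher in knockdown than in control cells with and without IFNγ.

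The comparison of shSdc1 with shRFP without IFNγ asks what the Sdc1 knockdown did to resting cells. Pigment-cell genes fell, and genes for extracellular matrix, chemokines and targets of MAP kinase signalling rose. Pmel, the structural protein of melanosome fibrils, fell from 4394 ± 48.6 to 1798 ± 52.03 CPM, a log2 fold change of -1.29 ± 0.05. Fn1, which encodes fibronectin, rose from 63.8 ± 5.39 to 295 ± 6.19 CPM (2.21 ± 0.05 on the log2 scale). Cxcl1, a chemokine for neutrophils, rose from 0.393 ± 0.139 to 8.17 ± 0.399 CPM (4.29 ± 0.27). In all, 4024 genes passed the test, 1969 higher and 2055 lower in the knockdown; 324 were at least 2-fold higher and 161 at least 2-fold lower.

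Of the 21 melanocyte and pigmentation genes measured, 19 fell, 0 rose and 2 did not pass, and 19 fell when adjusted over the list alone. The log2 fold changes were -1.97 ± 0.20 for Oca2, a melanosomal transporter, -1.48 ± 0.05 for the channel gene Trpm1 and -1.17 ± 0.05 for Tspan10 (camera adjusted p = 1.18e-28 for the list). Of 24 genes for extracellular matrix and matrix proteases, 19 rose, 2 fell and 3 did not pass, and adjusted over the list alone the counts were the same (camera adjusted p = 1.7e-21). Spp1, which encodes osteopontin, rose by 2.65 on the log2 scale from a low level, while Col1a2, a collagen I chain, changed by -1.70. Of 16 immediate early and MAPK-responsive genes, 9 rose, 1 fell and 6 did not pass, with 10 higher and 1 lower adjusted over the list alone (camera adjusted p = 9.19e-09). They included the transcription factors Etv4 (2.77) and Etv5 (2.42), and Spry4 (2.51) and Dusp5 (1.64), which are feedback inhibitors of the pathway.

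Chemokine genes rose in 6 of 10 cases with 0 lower (7 higher adjusted over the list alone; camera adjusted p = 2.08e-05), among them the CXCR3 ligand Cxcl10 (0.90 ± 0.08) and Ccl5 (0.91 ± 0.14). Of 15 cytokine and growth factor genes, 7 rose, 1 fell and 7 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.00448). The alarmin Il33 (1.70), Tgfb1 (1.41) and the macrophage growth factor Csf1 (1.14) were among those that rose. NF-kB target genes rose in 7 of 13 cases and fell in 1 (9 and 1 adjusted over the list alone; camera adjusted p = 0.000543, adjusted p = 0.0782 with an estimated correlation). Tnfaip3 (1.02) and Nfkbia (0.58), both inhibitors of the pathway, were among them. Integrin genes rose in 6 of 13 cases and fell in 1, with the same counts adjusted over the list alone (camera adjusted p = 0.00186), led by Itgb8 (1.998) and Itga5 (1.29). Of 11 genes of epithelial-mesenchymal transition and invasive states, 6 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.00103, adjusted p = 0.0782 with an estimated correlation); the receptor kinase Axl (0.96) rose and the transcription factor Sox9 (-1.55) fell. Of 13 genes of the syndecan and glypican list, 8 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.0308, adjusted p = 0.194 with an estimated correlation), with Sdc3 (0.80), Gpc4 (1.88) and the collagen XVIII gene Col18a1 (2.57) higher.

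In the list of the unfolded protein and integrated stress response, 15 of 25 fell, 4 rose and 6 did not pass (16 lower and 4 higher adjusted over the list alone; camera adjusted p = 1.68e-10). Chac1 (-1.18), Trib3 (-1.13) and asparagine synthetase, Asns (-0.87), were among those that fell, all targets of ATF4. Hypoxia and glycolysis genes fell in 17 of 28 cases and rose in 1 (19 and 2 adjusted over the list alone; camera adjusted p = 0.000118, adjusted p = 0.153 with an estimated correlation), with Ndrg1 (-0.86) as an example. Of 27 genes for cholesterol and lipoprotein uptake, 14 fell and 3 rose (18 and 3 adjusted over the list alone; camera adjusted p = 0.0166, adjusted p = 0.225 with an estimated correlation), including Tm7sf2 (-0.59) and Msmo1 (-0.37) of sterol synthesis. Of 37 cell cycle genes, 7 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.0371, adjusted p = 0.429 with an estimated correlation), with the cyclin Ccnd1 (1.43) highest among the examples.

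In the MHC class I list 8 of 21 rose and 1 fell (9 and 1 adjusted over the list alone; camera adjusted p = 0.00505), with the peptidase Erap1 (0.76), the immunoproteasome subunit Psmb10 (0.74) and Tapbp (0.60) higher. H2-D1, a class I heavy chain, changed by -0.26 ± 0.06 (edgeR adjusted p = 0.0032), H2-K1 by -0.17 ± 0.12 (edgeR adjusted p = 0.33) and B2m, the light chain, by 0.03 ± 0.03 (edgeR adjusted p = 0.46). The transcription factor Irf1 rose by 0.48 ± 0.08. Cd274, which encodes the checkpoint ligand PD-L1, changed by -0.40 ± 0.11 (edgeR adjusted p = 0.0092), and the IFNγ receptor gene Ifngr1 by 0.05 ± 0.09 (edgeR adjusted p = 0.72). Over 21 alternatives the adjusted p of Cd274 ranged from 0.00318 to 0.0664, and its call ended without shRFP replicate 1 or shSdc1 replicate 3.

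The other 11 lists tested did not pass. Among them, 8 of 30 type I interferon-stimulated genes rose and 5 fell (9 and 5 adjusted over the list alone; camera adjusted p = 0.181), among them Dhx58 (0.91) higher and Cmpk2 (-0.81) lower, and 4 of 15 genes for guanylate-binding proteins and related GTPases rose, with a median log2 fold change of 0.363 and a mean of -0.0561. Of 16 leukocyte marker genes listed, only 2 were kept by the filter on low counts. Both rose in the knockdown, Cd68 from 2.45 ± 0.506 to 7.25 ± 0.316 CPM and Lyz2 from 0.511 ± 0.167 to 1.35 ± 0.184 CPM. The largest falls by the rule for named genes included Sema6d (-2.99), Gjb2 (-2.63), Gsto1 (-2.25) and Nupr1 (-1.60), besides Oca2, Col1a2 and Sdc1. The largest rises, besides Cxcl1 and Etv5, were in the amino acid transporter Slc38a3 (4.73), Serpinb1a (3.496), Xdh (3.34), Sema3f (2.64), Serpinb9b (2.60) and Cfap70 (2.58). Without a fold minimum upward and downward calls were close in number, and scaling by DESeq2 size factors gave 2037 higher and 1985 lower. In shSdc1 replicate 3 a single Ensembl gene without a symbol in the reference, ENSMUSG00000119584, held 4.79% of the counts, against 0.0842 to 0.195% in the other 11 libraries.

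**Figure D2:**
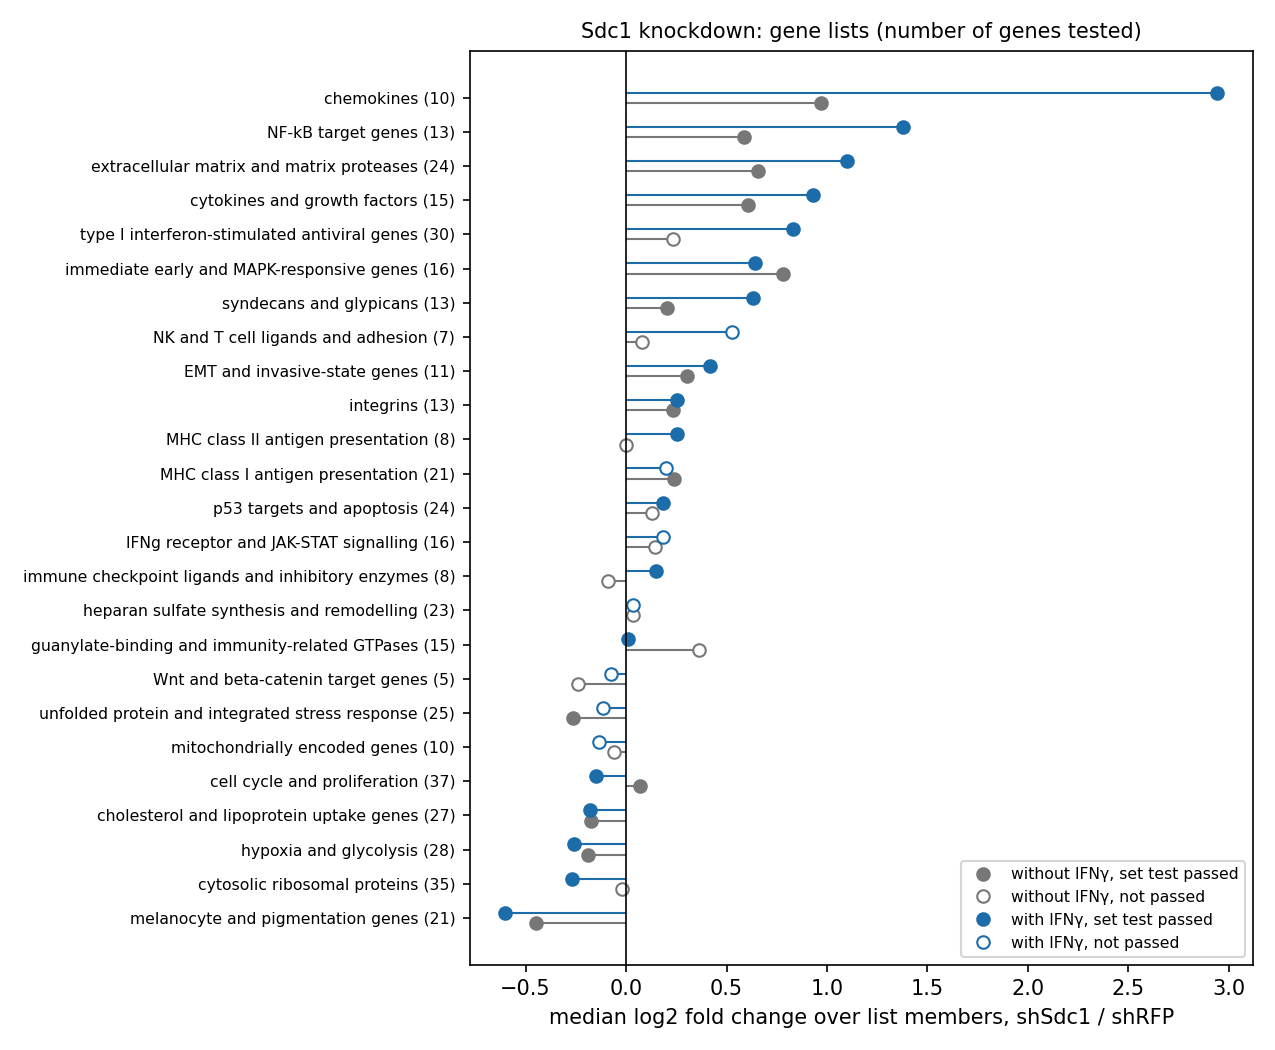
Median log2 fold change of shSdc1 over shRFP in each of the 25 gene lists tested, grey without IFNγ and blue with it; filled points passed the set test. The melanocyte list lay at -0.448 without and -0.6 with IFNγ, and the chemokine list at 0.968 and 2.94.

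The same comparison in cells given IFNγ asks whether the Sdc1 knockdown changed the stimulated state. The chemokines for T cells rose, together with type I interferon-stimulated genes and NF-kB targets, and pigment genes fell again. Cxcl9 rose from 13.4 ± 0.330 to 75.8 ± 1.62 CPM, a log2 fold change of 2.49 ± 0.08, Cxcl10 from 308 ± 2.99 to 681 ± 13.4 CPM (1.15 ± 0.05) and Ccl5 from 19.3 ± 1.58 to 77.6 ± 2.08 CPM (2.01 ± 0.09). H2-K1 rose from 263 ± 26.3 to 343 ± 22.2 CPM (0.39 ± 0.06), and Pmel fell from 4300.0 ± 237 to 1524 ± 119 CPM (-1.50 ± 0.05). In all, 5121 genes passed, 2668 higher and 2453 lower in the knockdown; 540 were at least 2-fold higher and 107 at least 2-fold lower.

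Of 10 chemokine genes, 9 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 9.42e-33), including the third CXCR3 ligand, Cxcl11 (3.38), and Cxcl1 (3.96). Of 30 type I interferon-stimulated antiviral genes, 27 rose and 0 fell, with 28 higher adjusted over the list alone (camera adjusted p = 1.62e-36). The largest were in the synthetase family that activates RNase L, Oas3 (1.72 ± 0.458 to 23.2 ± 1.77 CPM, 3.75 ± 0.19), Oas2 (1.74) and the related Oasl1 (1.78), and in Ifi44 (2.999). NF-kB targets rose in 10 of 13 cases with 0 lower (12 higher adjusted over the list alone; camera adjusted p = 2.26e-14), among them Bcl3 (2.34), Tnfaip3 (1.59) and Relb (1.55). Cytokine and growth factor genes rose in 10 of 15 cases with 0 lower (11 higher adjusted over the list alone; camera adjusted p = 1.1e-06).

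In the MHC class I list 12 of 21 rose and 3 fell (12 and 4 adjusted over the list alone), but the list did not pass (camera adjusted p = 0.0728). H2-D1 changed by 0.24 ± 0.05, the peptide transporter Tap1 by 0.27 ± 0.05 and the class I regulator Nlrc5 by 0.33 ± 0.06. Tap2, the other subunit of the transporter, fell from 57.8 ± 2.40 to 36.5 ± 2.20 CPM (-0.67 ± 0.07). B2m changed by -0.03 ± 0.03 (edgeR adjusted p = 0.49). In the MHC class II list 4 of 8 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.00848, adjusted p = 0.134 with an estimated correlation), with the invariant chain Cd74 (0.72) and H2-Aa (0.56) higher, and their regulator Ciita changed by 0.07 ± 0.08 (edgeR adjusted p = 0.57). Guanylate-binding and related GTPase genes went both ways, 7 of 15 higher and 4 lower (7 and 5 adjusted over the list alone; median 0.012; camera adjusted p = 0.0303, adjusted p = 0.134 with an estimated correlation), with Gbp5 (2.11) and Gbp9 (1.37) higher. Among 16 genes of the IFNγ receptor and JAK-STAT pathway 7 rose and 0 fell, and the list did not pass; Irf1 changed by -0.07 ± 0.05 (edgeR adjusted p = 0.35). Of 8 immune checkpoint genes 3 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.0139, adjusted p = 0.0689 with an estimated correlation). The gene that fell was Cd274, by -0.16 ± 0.06 (edgeR adjusted p = 0.043, 0.0176 to 0.167 over 21 alternatives). Its call ended with upper-quartile scaling, with DESeq2, and without replicate 1 or 2 of shRFP with IFNγ or replicate 2 or 3 of shSdc1 with IFNγ.

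Pigmentation genes fell in 18 of 21 cases with 0 higher (19 lower adjusted over the list alone; camera adjusted p = 8.21e-35), Trpm1 by -1.66 ± 0.06. Matrix genes rose in 21 of 24 cases and fell in 1, also adjusted over the list alone (camera adjusted p = 2.97e-27), with Fn1 at 2.30 ± 0.05, Spp1 (3.43) and thrombospondin, Thbs1 (2.43). Integrin genes rose in 8 of 13 cases and fell in 2, also adjusted over the list alone (camera adjusted p = 0.000482). Genes of invasive states rose in 8 of 11 cases with 0 lower (8 and 1 adjusted over the list alone; camera adjusted p = 4.82e-08), with Axl (1.71) among them. Syndecan and glypican genes rose in 9 of 13 cases and fell in 2, also adjusted over the list alone (camera adjusted p = 0.00155, adjusted p = 0.0689 with an estimated correlation). Immediate early and MAPK-responsive genes rose in 10 of 16 cases and fell in 2 (12 and 2 adjusted over the list alone; camera adjusted p = 0.000829, adjusted p = 0.0544 with an estimated correlation), with Egr1 (3.56) highest among the examples.

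Of 35 genes for cytosolic ribosomal proteins 31 fell and 0 rose (32 lower adjusted over the list alone; median -0.267; camera adjusted p = 6.75e-09, adjusted p = 0.134 with an estimated correlation), such as Rps27 (-0.44), Rpl32 (-0.39) and Rpl7 (-0.38). Of 37 cell cycle genes 22 fell and 2 rose (24 and 2 adjusted over the list alone; median -0.148; camera adjusted p = 0.00848, adjusted p = 0.275 with an estimated correlation), including E2f2 (-0.43) and the mitotic kinase Plk1 (-0.35). Hypoxia and glycolysis genes fell in 19 of 28 cases and rose in 1 (20 and 1 adjusted over the list alone; camera adjusted p = 1.34e-05, adjusted p = 0.102 with an estimated correlation). Cholesterol genes fell in 16 of 27 cases and rose in 3 (18 and 3 adjusted over the list alone; camera adjusted p = 0.000642, adjusted p = 0.102 with an estimated correlation). The largest rises by the rule for named genes were in the complement gene C3 (0.0831 ± 0.144 to 10.3 ± 2.20 CPM), Serpinb1a (4.79), Lrig1 (4.33) and Slc38a3 (3.996) and the costimulatory receptor Tnfrsf9 (3.74), besides Cxcl1, Oas3 and Spp1. C3 had a log2 fold change of 6.76 ± 0.54 from 4 counts over the control group, all in replicate 2 of shRFP with IFNγ; without that library the rise was at least 101.8-fold, against 3 counts over the other 2. The largest falls included Sema6d (-2.61), Gsto1 (-2.40), Gjb2 (-2.11), Oca2 (-1.99), Smim11 (-1.73) and Arhgef37 (-1.71), besides Sdc1. Both leukocyte marker genes measured rose again, Cd68 from 6.32 ± 1.56 to 14.4 ± 0.380 CPM and Lyz2 from 0.740 ± 0.276 to 1.76 ± 0.227 CPM.

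The knockdown effects with and without IFNγ, measured on different libraries, shared 1184 genes that rose and 1199 that fell, against 372.9 and 357.8 by chance. Only 71 genes rose without IFNγ and fell with it, and 45 did the opposite. Across genes, which are not independent replicates, the log2 fold changes correlated with r = 0.618.

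IFNγ in control cells asks how the line responds when syndecan-1 is present. Antigen presentation and interferon genes rose together. H2-K1 rose from 6.05 ± 0.690 to 263 ± 26.3 CPM, a log2 fold change of 5.42 ± 0.09, B2m from 245 ± 5.20 to 1856 ± 9.77 CPM (2.92 ± 0.03) and Cd274 from 6.66 ± 0.740 to 75.9 ± 2.32 CPM (3.497 ± 0.08). Irf1 rose from 11.7 ± 1.53 to 380.3 ± 17.96 CPM (5.04 ± 0.07). In all, 4446 genes passed, 2422 higher and 2024 lower, of which 412 rose and 158 fell by at least 2-fold; upper-quartile scaling turned the balance to 1759 higher and 2811 lower.

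In the MHC class I list 20 of 21 rose and 0 fell (20 and 1 adjusted over the list alone; camera adjusted p = 5.92e-211), with Tap1 at 7.09 ± 0.08, Nlrc5 at 6.36 ± 0.08 and Psmb9 (9.69). In the MHC class II list 7 of 8 rose, also adjusted over the list alone (camera adjusted p = 7.69e-55). The fitted median of the list, 8.98, depends on the prior count where genes held 0 counts in shRFP. H2-Aa was at least 430.1-fold higher, H2-Ab1 at least 393.7-fold and H2-Eb1 at least 585-fold, since shRFP held 0 counts and the bound takes 3 counts over the group; Ciita rose by 9.19 ± 0.22 from 4 counts over the group, with a ratio of counts of 1515 (95% interval 271.7 to 59870) without shRFP replicate 1, where 1 count was left. All 15 genes for guanylate-binding proteins and related GTPases rose, also adjusted over the list alone, among them Iigp1 (13.18 ± 0.15). For Iigp1 this SE is smaller than the counting error. Without shRFP replicate 1, 3 counts were left in shRFP and its ratio of counts was 9762 (95% interval 3340 to 47340). Gbp4, Tgtp1 and Tgtp2 rose from 1 to 3 counts over the shRFP group. The ratios of counts were 28160 for Gbp4 (95% interval 5054 to 1112000), 9834 for Tgtp1 (2722 to 81210) and 13420 for Tgtp2 (4591 to 65070). All 30 type I interferon-stimulated genes rose, also adjusted over the list alone (median 3.58; camera adjusted p = 1.87e-176), with Oasl2 (8.69) as an example. Among genes of the IFNγ receptor and JAK-STAT pathway 11 of 16 rose and 0 fell (12 higher adjusted over the list alone; camera adjusted p = 1.43e-36). The receptor genes changed by -0.14 ± 0.09 for Ifngr1 (edgeR adjusted p = 0.28) and -0.03 ± 0.07 for Ifngr2 (edgeR adjusted p = 0.74).

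Of 10 chemokine genes 6 rose and 0 fell (7 higher adjusted over the list alone; camera adjusted p = 9.54e-14). Cxcl10 rose by 5.08 ± 0.07 and Ccl5 by 2.33 ± 0.12, and Cxcl9 from 3 counts over the shRFP group, a ratio of 238.7 (81.3 to 1161). Of 8 immune checkpoint genes 4 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 4.21e-08), including Tnfrsf14 (5.29) and Lgals9 (1.40) besides Cd274. Cholesterol genes rose in 23 of 27 cases with 0 lower (24 and 1 adjusted over the list alone; camera adjusted p = 4.64e-06, adjusted p = 0.0544 with an estimated correlation), such as Hsd17b7 (0.71) and Dhcr7 (0.66) of sterol synthesis. In the stress response list 13 of 25 fell and 5 rose (13 and 6 adjusted over the list alone; camera adjusted p = 2.68e-07), with Chac1 (-1.88), Trib3 (-1.83), Herpud1 (-1.10) and Asns (-1.08) lower. Sdc1 rose by 0.23 ± 0.07 (edgeR adjusted p = 0.024, 0.00106 to 0.147 over 21 alternatives), and the call ended with upper-quartile scaling and without shRFP replicate 2 or replicate 3 of shRFP with IFNγ, where the value was 0.11. Other lists did not pass, among them cell cycle with 22 of 37 higher and 6 lower (camera adjusted p = 0.333) and NF-kB targets with 2 of 13 higher and 4 lower. The largest falls by the rule for named genes, besides Chac1 and Trib3, were in Hoxb9 (-2.18), Chd5 (-1.82), Nupr1 (-1.78), Cabp1 (-1.77) and Pck2 (-1.39) and in Gapdh, which stood at 75.5, 481.3 and 452.9 CPM in the 3 shRFP libraries and at 44.9 ± 3.13 CPM with IFNγ. The remaining large rise was in Apol6, at least 811-fold higher.

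IFNγ in knockdown cells asks the same question with syndecan-1 reduced. H2-K1 rose from 5.41 ± 0.187 to 343 ± 22.2 CPM (5.99 ± 0.09 on the log2 scale), Cd274 from 5.10 ± 0.510 to 67.8 ± 3.31 CPM (3.73 ± 0.08) and Ccl5 from 7.16 ± 0.913 to 77.6 ± 2.08 CPM (3.44 ± 0.10). Irf1 rose by 4.50 ± 0.07, B2m by 2.85 ± 0.03 and Cxcl10 by 5.32 ± 0.07. Cxcl9 rose from 1 count over the shSdc1 group, a ratio of 3696 (95% interval 662.9 to 146000). In all, 4295 genes passed, 2469 higher and 1826 lower, of which 549 rose and 92 fell by at least 2-fold; upper-quartile scaling gave 2047 higher and 2495 lower.

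The MHC class I list rose in 19 of 21 cases (camera adjusted p = 2.42e-183) and the class II list in 7 of 8 with 1 lower (camera adjusted p = 2.34e-52). The fitted median of the class II list, 9.1, depends on the prior count where genes held 0 counts in shSdc1. All 15 guanylate-binding and related GTPases and all 30 type I interferon-stimulated genes rose (camera adjusted p = 2.19e-239 for the latter). Adjusted over the list alone the counts of all these lists were the same. Tap1 rose by 7.12 ± 0.08, and Iigp1 and Tgtp2 by 13.000 and 12.84. Tgtp1 was at least 5508-fold higher, Zbp1, a sensor of nucleic acids, at least 3496-fold, Gbp10 at least 1256-fold, Gbp9 at least 1161-fold and H2-Eb1 at least 613-fold. Chemokine genes rose in 9 of 10 cases with 0 lower (camera adjusted p = 3.18e-32), IFNγ receptor and JAK-STAT genes in 12 of 16 with 0 lower (camera adjusted p = 1.18e-34) and checkpoint genes in 5 of 8 with 0 lower (camera adjusted p = 1.38e-09), the last including Tnfrsf14 (4.05) and the don't-eat-me signal Cd47 (1.28); the 3 counts were the same adjusted over the list alone. Cytokine genes rose in 6 of 15 cases and fell in 1 (7 and 1 adjusted over the list alone; camera adjusted p = 0.0042).

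NF-kB targets rose in 9 of 13 cases with 0 lower (11 higher adjusted over the list alone; camera adjusted p = 0.0134, adjusted p = 0.236 with an estimated correlation), among them Bcl3 (2.45) and Nfkbie (1.15). Cholesterol genes rose in 23 of 27 cases with 0 lower, also adjusted over the list alone (camera adjusted p = 0.000508, adjusted p = 0.125 with an estimated correlation), such as Tm7sf2 (0.79) and Fdft1 (0.57). Pigmentation genes fell in 12 of 21 cases and rose in 2, also adjusted over the list alone (camera adjusted p = 0.0398, adjusted p = 0.497 with an estimated correlation), such as Tspan10 (-0.47) and Slc45a2 (-0.43). Ribosomal protein genes fell in 25 of 35 cases and rose in 1 (26 and 1 adjusted over the list alone; camera adjusted p = 0.00176, adjusted p = 0.497 with an estimated correlation), Rps27 (-0.76) and Rpl37 (-0.49) among them. Stress response genes fell in 10 of 25 cases and rose in 2 (12 and 2 adjusted over the list alone; camera adjusted p = 0.0381, adjusted p = 0.419 with an estimated correlation), where Chac1 (-0.82) fell and the stress factor Atf3 (1.28) rose. Sdc1 changed by 0.12 ± 0.09 (edgeR adjusted p = 0.33). The largest falls by the rule for named genes were in Abca12 (-1.85), Hoxa11 (-1.28), Etv5 (-1.21), Prss12 (-1.15), Rpl38-ps2 (-1.08), Fam81a (-1.08), Npnt (-1.06) and Mex3b (-0.999). In 1 of the largest rises, Gbp4, the ratio of counts was 20240 (3632 to 799400).

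The responses to IFNγ in control and knockdown cells, also measured on different libraries, shared 1415 genes that rose and 734 that fell, against 424.4 and 262.3 by chance, and their log2 fold changes correlated across genes with r = 0.875.

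**Figure D3:**
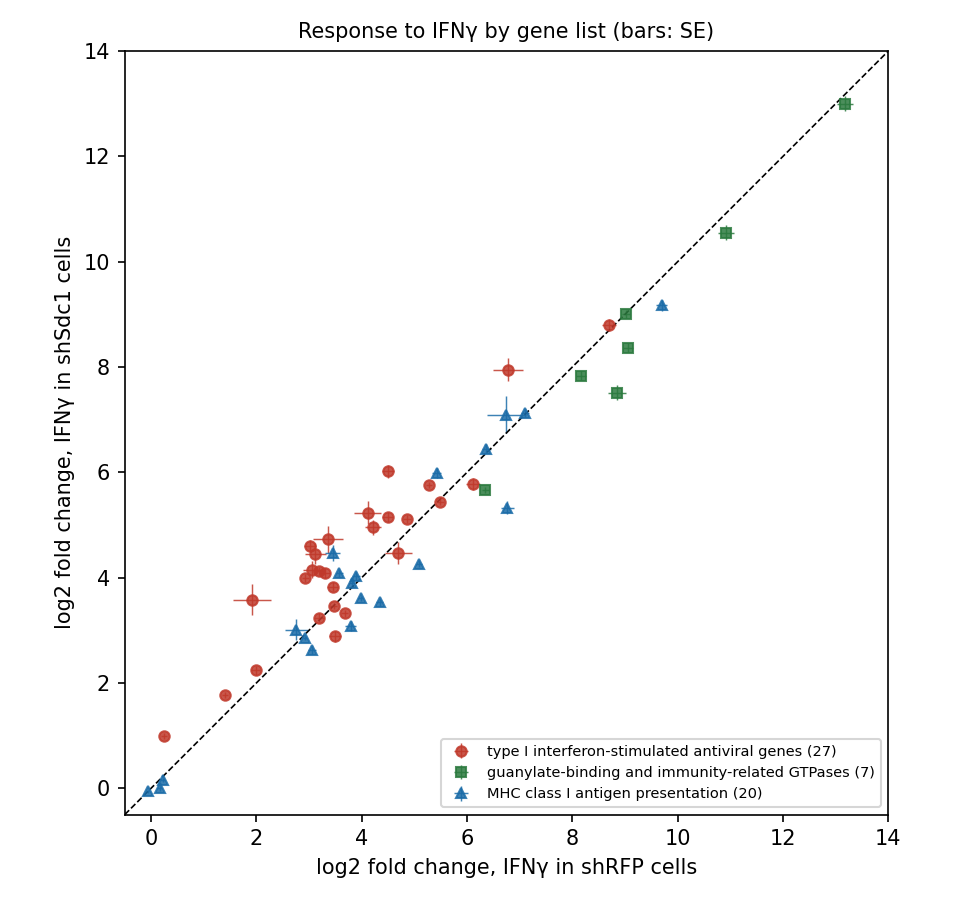
Log2 fold change with IFNγ in control cells (horizontal) and knockdown cells (vertical), 1 point per gene of 3 lists; genes with at most 3 counts over an unstimulated group are left out. Of the type I interferon-stimulated genes plotted, 21 of 27 lay above the diagonal, against 10 of 20 for MHC class I and 0 of 7 for guanylate-binding and related GTPases. Those left out were 3 of 30, 1 of 21 and 8 of 15 genes, so the last count does not describe its list.

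The interaction, the knockdown effect with IFNγ minus that without, asks where the cytokine changed the effect of the Sdc1 knockdown. Positive values mean a signed knockdown effect that was higher with IFNγ, such as a larger rise or a smaller fall, and negative values the reverse. Among the genes of central interest that passed, Ccl5 had the highest value, 1.10 ± 0.17 (edgeR adjusted p = 5.2e-04), and the class I heavy chains gave 0.51 ± 0.08 for H2-D1 (edgeR adjusted p = 9.1e-04) and, for H2-K1, 0.56 ± 0.14 (edgeR adjusted p = 0.016). Irf1 changed by -0.55 ± 0.10 (edgeR adjusted p = 0.0019). The value for Cxcl9 was 3.68 ± 1.20 (edgeR adjusted p = 0.072) from at most 3 counts over each unstimulated group; it passed with limma-voom (adjusted p = 0.0126) and without shRFP replicate 1 (adjusted p = 0.0424). The value for Cxcl10 was 0.24 ± 0.09 (edgeR adjusted p = 0.11), which passed without shSdc1 replicate 3 (adjusted p = 0.0498), and for Cd274 0.23 ± 0.12 (edgeR adjusted p = 0.24). In all, 1371 genes passed, 645 with a positive and 726 with a negative difference, and 707 and 631 with upper-quartile scaling. Of the 108 that differed by at least 2-fold, 84 were positive and 24 negative.

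Of 30 type I interferon-stimulated genes 11 had a positive and 2 a negative interaction (16 and 2 adjusted over the list alone; median 0.74; camera adjusted p = 1.07e-08, adjusted p = 0.0706 with an estimated correlation). Mx1, an antiviral GTPase, stood at 3.64 ± 0.533 CPM in shRFP, 2.46 ± 0.679 in shSdc1, 29.7 ± 1.35 in shRFP with IFNγ and 59.8 ± 3.60 in shSdc1 with IFNγ, and its interaction was 1.58 ± 0.19; that of Ifit3b was 1.51 ± 0.23. NF-kB targets had 5 positive and 0 negative of 13 (6 positive adjusted over the list alone; camera adjusted p = 1.07e-08, adjusted p = 0.0695 with an estimated correlation), with Relb (0.93) and Nfkbia (0.79). The stress response list had 13 positive and 1 negative of 25 (14 and 3 adjusted over the list alone; camera adjusted p = 1.07e-08, adjusted p = 0.0706 with an estimated correlation), with Trib3 (1.28) and Chac1 (1.07). Without IFNγ, Trib3 stood at 132.3 to 147.1 CPM in shRFP and 59.5 to 67.5 in shSdc1. With IFNγ it stood at 35.8 to 43.7 CPM in shRFP and 39.1 to 48.2 in shSdc1. Chac1 also fell in the knockdown without IFNγ, and its group ranges overlapped with IFNγ. The list of invasive states had 2 positive and 0 negative of 11 (4 positive adjusted over the list alone; camera adjusted p = 0.00425, adjusted p = 0.163 with an estimated correlation), Axl (0.75) among them. Matrix genes had 5 positive and 3 negative of 24 (7 and 3 adjusted over the list alone; camera adjusted p = 0.0256, adjusted p = 0.319 with an estimated correlation), with Thbs1 (1.31); without shSdc1 replicate 3, an alternative chosen after seeing the data, the camera adjusted p was 0.0613.

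Ribosomal protein genes had 23 negative and 0 positive interactions of 35 (32 and 1 adjusted over the list alone; median -0.211; camera adjusted p = 4.12e-13, adjusted p = 0.163 with an estimated correlation), with Rps27 (-0.67) and Rps18 (-0.42). Cell cycle genes had 17 negative and 0 positive of 37 (26 negative adjusted over the list alone; median -0.201; camera adjusted p = 1.39e-10, adjusted p = 0.0706 with an estimated correlation), with the cyclin Ccne1 (-0.54) and the replication clamp Pcna (-0.35). Pigmentation genes had 6 negative and 0 positive of 21 (8 negative adjusted over the list alone; camera adjusted p = 0.00166, adjusted p = 0.327 with an estimated correlation), with Gpr143 (-0.50) and Slc45a2 (-0.33). In the MHC class I list 3 of 21 were positive and 6 negative, also adjusted over the list alone (camera adjusted p = 0.0361, adjusted p = 0.163 with an estimated correlation). The median of that list was 0.00225 (-0.00634 with DESeq2 size factors) and its mean -0.104, and the test was in the negative direction, with Psmb10 (-0.84) and Erap1 (-0.81) opposite to the heavy chains. Guanylate-binding and related GTPases had 3 negative and 0 positive of 15 (median -0.328, mean 0.335; camera adjusted p = 0.0852).

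By the rule for named genes the largest positive interactions were in Inpp1 (1.92), Hoxb9 (1.83), Cebpd (1.83) and Chd5 (1.74), and the largest negative ones in the peptide transporter subunit Tap2 (-1.43), Clec2d (-1.41) and the GTPase Ifi47 (-1.53), which stood at -2.14 without shRFP replicate 1. Tap2, Clec2d and Ifi47 were under 1 CPM in every shRFP library without IFNγ, and Clec2d was higher in the knockdown in both states. Apol9a, Casp12, Sarnp, Gapdh and Pacsin1 met the rule too, with calls that ended when single libraries were left out. The number of genes fell from 1371 to 847 without shRFP replicate 1, 839 without shRFP replicate 2, 789 without shSdc1 replicate 1 and 822 without replicate 2 of shSdc1 with IFNγ. The call of H2-K1 ended with limma-voom (adjusted p = 0.115) and without shRFP replicate 1 or 2 or shSdc1 replicate 3 (0.0537 to 0.0641); the lowest adjusted p over 20 alternatives was 0.000245.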

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

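The test on the other glycolytic genes was chosen only after its result was seen. The IFNγ treatment changed the knockdown effect of 1371 genes by a test of the difference itself, and all values here are log2 differences, knockdown effect with IFNγ minus that without. Of 100 splits of the libraries, the real one included, 2 gave as many genes; the highest other split gave 5717 and the next 1246. The split with 5717 exchanged knockdown and control among the IFNγ libraries, which adds the knockdown effects where the real split subtracts them, a structure of the samples. Most other splits mixed knockdown and control cells in both treatments, which puts the knockdown effect into the spread, and 79 of these 80 gave 0 genes. The 18 that mixed them in 1 treatment gave up to 1246. The splits therefore do not decide whether chance can be excluded. The other comparisons allow 10 splits, too few for a share under 0.05. In each of them 1 split, the real one, gave as many genes, with 4024, 5121, 4446 and 4295 genes and 0 in the highest other split.

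Among genes of central interest the difference was 1.10 for Ccl5, 0.56 for H2-K1, 0.51 for H2-D1 and -0.55 for Irf1. The call of H2-K1 ended with limma-voom (adjusted p = 0.115) and without shRFP replicate 1 or 2 or shSdc1 replicate 3. Among interferon and antigen presentation genes it was 1.58 for Mx1, 1.51 for Ifit3b, 0.50 for Stat2, -1.43 for Tap2, -0.84 for Psmb10, -0.81 for Erap1, -0.69 for Irgm1 and -1.53 for Ifi47. Psmb10, Erap1 and Irgm1 were higher in every knockdown library than in any control library without IFNγ. With IFNγ Psmb10 and Irgm1 were lower in the knockdown, and the ranges of Erap1 overlapped. For Clec2d, the ligand of an inhibitory NK cell receptor, the difference was -1.41, and for the checkpoint gene Cd47 0.59. Clec2d was higher in the knockdown in both states. Without IFNγ it stood at 0.276 to 0.593 CPM in shRFP and 2.00 to 3.52 in shSdc1. With IFNγ it stood at 10.9 to 11.8 CPM in shRFP and 21.3 to 25.3 in shSdc1. Its negative value is thus a smaller rise, from a low starting level. NF-kB genes gave 0.93 for Relb and 0.79 for Nfkbia, matrix and invasive-state genes 1.31 for Thbs1 and 0.75 for Axl, and stress genes 1.28 for Trib3 and 1.07 for Chac1. Trib3 and Chac1 fell in the knockdown without IFNγ, while with IFNγ the ranges of knockdown and control overlapped. Their positive values thus mark the loss of a fall. Pigmentation genes gave -0.50 for Gpr143 and -0.33 for Slc45a2, MAP kinase targets -1.21 for Etv5 and -0.75 for Dusp6, and cell cycle genes -0.54 for Ccne1 and -0.35 for Pcna. Etv5 and Dusp6 were higher in the knockdown in both states, so their negative values mark smaller rises. The remaining genes by the rule were Inpp1 (1.92), Hoxb9 (1.83), Cebpd (1.83) and Chd5 (1.74).

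Besides H2-K1, 5 of the genes flagged here lost the call when single libraries were left out. Casp12 had a difference of -4.18, a fitted value that depends on the prior count since shRFP held 0 counts, and its call ended without shRFP replicate 1 or 2 (adjusted p 0.00819 to 0.0749 over 20 alternatives). Apol9a had -2.02, or -1.31 without shRFP replicate 1, and its call ended there, without shSdc1 replicate 1 or 2, with limma-voom and with the DESeq2 Wald test (0.0196 to 0.226). Apol9a stood at 0 to 0.138 CPM in shRFP and was higher in the knockdown both with and without IFNγ. Sarnp, with -1.57, lost its call without shRFP replicate 2 or 3, shSdc1 replicate 1, replicate 1 of shRFP with IFNγ, or replicate 1 or 2 of shSdc1 with IFNγ, and with the DESeq2 Wald test (4.58e-19 to 0.102). Pacsin1, with 1.80, lost it without shRFP replicate 1 or 2 or shSdc1 replicate 2 or 3 (0.00327 to 0.116), and stood at 2.46 without shSdc1 replicate 1. Gapdh had 2.25 and lost its call in 11 of 20 alternatives, limma-voom and the DESeq2 Wald test among them; the other 9 left out a library, any but shRFP replicate 1, shSdc1 replicate 2 and replicate 3 of shRFP with IFNγ (8.17e-164 to 0.161).

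Ribosomal protein genes were lower in the knockdown with IFNγ, and their interaction was -0.67 for Rps27 and -0.42 for Rps18. Their annotated exons, joined over all transcripts of a gene, are short (median 2015 bases, against 4163 in other genes). A length bias was therefore tested with 10000 random lists matched for this length and for mean expression. The matched lists had a median of -0.126 (95% of them between -0.200 and -0.0522), and 4 of 10000 lay as low as the -0.267 of the ribosomal list. On this measure a trend with length, with expression level or with both could account for a part of the fall. The lists do not tell these apart. Joined exons are not the length of the expressed transcript, so the test cannot exclude a length bias as the cause of the rest. For the interaction the lists matched for length and expression had a median of -0.141 (-0.194 to -0.0896) against -0.211 in the ribosomal list. Of these lists 58 of 10000 lay as low. A trend with length or expression level could account for most of that difference. Lists matched for GC content and mean expression had a median of -0.0727 (-0.150 to -0.00397), and 0 of 10000 lay as low in the knockdown with IFNγ. For the interaction the median of lists so matched was -0.0868 (-0.143 to -0.0291). Slower growth is a hypothesis that was not tested and stays open, with 22 of 37 cell cycle genes lower in the same comparison. With an estimated correlation the calls of both lists are lost in the knockdown with IFNγ (camera adjusted p = 0.275 for cell cycle and 0.134 for the ribosomal list). In the interaction 0 of 25 lists passed with it.

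Gapdh stood at 75.5, 481.3 and 452.9 CPM in the 3 shRFP libraries. Reads shared with near-identical copies were tested with 157 annotated copies of at least 90% identity over at least 500 bases, 99 of them with counts. The copies held 713.6, 711.3 and 764.1 CPM in the same libraries and did not offset the excess. Gapdh with its copies changed by -0.224 on the log2 scale with IFNγ in control cells, from 1066 to 913.2 CPM. The copies alone held 729.7 CPM of this sum without IFNγ and 868.3 CPM with it. The sum therefore says little about Gapdh itself. Reads that match several copies equally and were not counted are not in the table, so the effect of shared reads and a change of the gene cannot be told apart. A change of glycolytic genes as a group is argued against, since the other 27 members of the list had a median of 0.171 with IFNγ in control cells and 0 fell by 1 or more.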

How the results depend on the processing

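The fits without the assembled loci and ENSMUSG00000119584, and camera without shSdc1 replicate 3, were chosen after seeing the data. Over 541 pairs of a named gene and a comparison, 10929 of 11283 alternative values kept direction and side of the threshold, 345 lost the call, 5 gained one and 4 reversed. Of the 524 calls 73 were lost in at least 1 alternative, all 73 with a library left out, and 22 of them were in the interaction, which had 73 calls. The 4 reversals were uncalled genes with a library left out: Ifngr2 with IFNγ in control cells (-0.0818 to 0.0315, positive without replicate 1 of shRFP with or without IFNγ), Ifngr1 in the knockdown without IFNγ (-0.0119 to 0.1061, negative without shSdc1 replicate 1) and Sdc1 in the interaction (-0.19 to 0.00737, positive without replicate 3 of shRFP with IFNγ); the cause was not tested. Requiring a 2-fold change left 485, 647, 570, 641 and 108 genes for the knockdown without and with IFNγ, IFNγ in control and knockdown cells, and the interaction, by construction. Leaving out single libraries gave 3215 to 4403, 4146 to 5166, 3445 to 4507, 3356 to 4738 and 789 to 1999 genes, and the cause was not tested. Lists passing with an estimated correlation were 8, 8, 8, 8 and 0, the correlation being the only change, and with fry, which asks a different question, 16 for IFNγ in control cells, 22 in knockdown cells and 14 for the interaction. A pairing of the samples by replicate number was not seen, which does not exclude one. Correlations of residuals were -0.227 to 0.145 within a number, with 3 of 18 pairs above 0.1, and -0.254 to 0.312 between numbers. As a block the replicate numbers gave 3720, 4847, 4185, 4018 and 1028 genes. Depth limits the folds of genes with at most 3 counts in a group to bounds or intervals.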

Other observations

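The tests on histone genes and on the response of whole lists to IFNγ were chosen only after their results were seen. Casp12, an inflammatory caspase, was at 0 counts in shRFP and at 0.675 ± 0.156 CPM in shSdc1, at least 12-fold higher, and rose with IFNγ to 9.31 ± 1.38 and 46.2 ± 2.49 CPM. Casp4 (3.04), the caspase that senses lipopolysaccharide inside cells, rose in the knockdown with IFNγ. Gsdmd, which forms pores in pyroptosis, rose with IFNγ by 2.88 ± 0.13 in control and 3.07 ± 0.12 in knockdown cells, and Mlkl, the executor of necroptosis, by 2.01 ± 0.05 in control and 1.82 ± 0.05 in knockdown cells. In the list of p53 targets and apoptosis genes 12 of 24 rose and 1 fell in the knockdown with IFNγ, also adjusted over the list alone (camera adjusted p = 0.000202, adjusted p = 0.134 with an estimated correlation). With IFNγ the list had 9 higher and 4 lower in control cells (median 0.0343, or -0.019 with upper-quartile scaling; 10 and 4 adjusted over the list alone; camera adjusted p = 0.0161, adjusted p = 0.466 with an estimated correlation) and 12 higher and 2 lower in knockdown cells (13 and 3; camera adjusted p = 6.06e-05, adjusted p = 0.192 with an estimated correlation).

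Some lists did not pass in the knockdown with or without IFNγ. Of 23 genes of heparan sulfate synthesis, the sugar chains that syndecans carry, 8 rose and 5 fell without IFNγ and 8 rose and 6 fell with it. Ligands for NK and T cells rose in 1 and fell in 1 of 7 genes without IFNγ, and rose in 4 and fell in 0 with it. Wnt targets had 0 higher and 2 lower of 5 in each case, and the 10 mitochondrially encoded genes 0 higher and 2 lower without and 1 higher and 2 lower with IFNγ. Of 2 markers of fibroblasts and endothelium measured 0 passed without IFNγ, and of 3 genes measured in a list of histones 1 fell, H1f0, which encodes a replication-independent linker histone. No listed keratinocyte or epithelial marker was kept by the filter on low counts.

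In shSdc1 replicate 3 ENSMUSG00000119584 held 803968 counts, 4.79% of the library, and Lars2, Hist1h4d and several assembled loci also stood far above the other 11 libraries. More non-polyadenylated RNA in it would raise histone transcripts, most of which end without a poly(A) tail. Of 29 histone genes with at least 5 counts over the 9 libraries of the other groups, 6 were among the loci that prompted the test. Of the other 23, 18 were higher in this library than in its group, with a median log2 excess of 2.27 (quartiles 0.124 to 4.17). That is 78.3%, below the 90% the explanation was set to need, so it stays open. A first choice of genes by counts in shSdc1 itself gave 25 of 27 and a median of 4.01, but let the excess pick the genes. More cells in S phase would raise cell cycle genes too, and this is argued against, as the 37 genes of that list had a median excess of -0.00967 (quartiles -0.0283 to 0.0256). No other biological explanation was tested, since the design gives none for a single library.

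A hypothesis for the type I interferon-stimulated genes is that they rose in the knockdown with IFNγ because these cells made more interferon. The 18 type I and III interferon genes in the table gave 1 count in shRFP with IFNγ and 0 in shSdc1 with IFNγ, a ratio of 0 with a 95% interval of 0 to 35.95, so the counts are too few to decide. A larger response of all IFNγ targets alike is argued against by the median of the MHC class I list, within limits. The median interaction of the type I list exceeded that of the MHC class I list by 0.738 (95% bootstrap interval 0.284 to 1.218). It exceeded that of guanylate-binding and related GTPases by 1.069 (0.0168 to 1.544), an interval that comes close to 0. In that GTPase list 8 of 15 genes had at most 3 counts over an unstimulated group, so their values depend on the prior count. The mean interaction of the GTPase list was positive, so it does not decide. The bootstrap takes genes as independent, so with correlated genes the intervals would be wider. With an estimated correlation 0 of 25 lists passed the set test in the interaction.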
